A study of Rattus norvegicus with 11 samples.

How the data were processed

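Total RNA of the 11 samples was labelled with biotin for Affymetrix Rat Gene 1.0 ST arrays. The values used here are log2 expression values, 1 per probe set and array, that the authors deposited as a single table. They were made with RMA, per the submitters' processing notes, which give the name alone, without version, options or software. All 11 columns of the table share a median of 8.97 while their quartiles differ. The arrays thus had a common median, the table as a whole was not quantile-normalized, and the step that set the median is unknown. Scanner files were not used here, so background, saturation and detection could not be examined per probe. RMA draws low values together, so that changes of dim genes are understated.

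The table held 29214 rows. The platform annotation given for this work paired 15310 rows with 1 gene symbol, 323 with several and 13581 with none, the last being unnamed here and not without a gene. Gene identifiers were looked up in a RefSeq table of the assembly GRCr8 for names only. There 15279 matched, and 0 symbols were updated. Genes with more than 1 row, 527 in all, were represented by the row with the highest mean over all arrays, which left 14506 genes. Rows with several symbols or none entered only an alternative. Coordinates are not reported here. No filter on dim genes was applied.

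Samples were grouped by culture and day from the labels. The same fit covered all 11 arrays: limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values, terms for day and for culture, and 6 residual degrees of freedom. It gave the 5 comparisons between days and that between the cultures. A second fit gave each of the 8 groups its own mean, with 3 residual degrees of freedom, all from the feeder-free pairs of days 7, 17 and 32. It gave the tests of whether a change differed between the cultures, and the contrast of the culture difference at day 0 with its mean over days 7, 17 and 32. The single feeder arrays are there assumed to vary like those pairs. P values were adjusted by the Benjamini-Hochberg method and called under 0.05. Changes are given on the log2 scale with the standard error of the fit, and a change within 1 culture is the difference of group means. The labels call the feeder-free pairs biological replicates without saying whether the cultures were separate, so the p values may measure technical spread.

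Before the data were examined, 22 gene lists were fixed: naive pluripotency, primed epiblast, hypoblast regulators, extraembryonic endoderm matrix and uptake, visceral endoderm, parietal endoderm, trophoblast, mesendoderm and mesoderm, neuroectoderm, epithelial junctions and keratins, mesenchymal, fibroblast, ERK targets, canonical Wnt targets, BMP targets, JAK-STAT targets, cholesterol synthesis, glycolysis, DNA methylation and germline, imprinted, cell cycle, and interferon and antigen presentation. They held 281 distinct measured genes, and some genes stand in more than 1 list. Each list was tested in each of the 7 comparisons with camera at a preset correlation of 0.01 and adjusted over the 22 lists. An estimated correlation and fry were alternatives. With the estimated correlation 1 of 67 list calls held, that of the ERK targets from day 7 to day 32.

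The rule for named genes was also fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes with the same sign in both cultures, or on all 4 days for the culture comparison, and 5 each way for the day 0 contrast. It added up to 4 called members per list, or the 2 with the largest change where none passed, and always Pou5f1, Nanog, Sox2, Gata4, Gata6, Sox17 and Pdgfra. The text prints a part of these genes. Genes for olfactory and vomeronasal receptors, 1240 in number, were taken as background after the data were seen.

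The calculation was tested on simulated data with 200 changed genes among 14506, drawn with the spread of the real arrays. For day 0 to day 7 it recovered 59.7% of genes changed by 1 on the log2 scale, 97% of those changed by 2 and 98.5% of those changed by 4, with 5 false calls among 175. For day 7 to day 17 the shares were 86.6%, 94% and 98.5%, for the culture comparison 88.1%, 97% and 100%, and for the day 0 contrast 64.2%, 95.5% and 100%. In the comparisons of days the simulated changes were equal in both cultures, with independent noise. Many real changes differed between the cultures, so these shares and false calls need not hold for the real data. The alternatives were a filter on the dimmest 25% of genes, the mean of all rows of a gene, all rows, a further quantile normalization, centring on the median of the genes, eBayes with trend and robust, array weights, a change of at least 1 on the log2 scale, the 8-group fit, a replicate block, no culture term, the feeder-free arrays alone, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.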

Results

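Gene expression was measured on 11 Affymetrix Rat Gene 1.0 ST arrays while rat embryonic stem cells of the line DAc2 were converted to hypoblast stem cells, named cHypoSCs in the labels. The hypoblast, or primitive endoderm, is the early embryonic layer that forms the extraembryonic endoderm of the yolk sac. The stem cells had been kept either without feeder cells, on laminin, or on a layer of mouse embryonic fibroblasts, and cells were collected at days 0, 7, 17 and 32. Both starting media held 3 µM CHIR99021, an inhibitor of GSK3, and the MEK inhibitor PD0325901, at 2 µM without feeder cells and at 0.5 µM on feeder cells. Only the feeder-free medium held BMP4, at 5 ng/mL. For conversion the cells were moved to a medium for multipotent progenitors, in which the serum share was 2% and the added factors were PDGF, EGF and LIF. The feeder-free arm had 1 array at day 0 and 2 at each of days 7, 17 and 32, called biological replicates in the labels. The feeder arm had 1 array per day, so its single values carry no spread of their own. Below, "on feeder cells" names the arm whose starting stem cells grew on feeder cells, on every day. The sample titles do not say whether feeder cells were present during the conversion.

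All 11 arrays shared a median of 8.97 on the log2 scale. The feeder-free replicates of a day correlated at 0.997 (day 7), 0.998 (day 17) and 0.998 (day 32) across genes, and no value was identical within a pair. The first principal component held 57.3% of the variance and ran from day 0 to days 17 and 32. On it the feeder array of day 7 lay at -55.5, beside the day 0 arrays at -70.5 (feeder) and -64.4 (feeder-free), whereas the feeder-free day 7 arrays lay at 7.78 and 9.01. Genes for olfactory and vomeronasal receptors, mostly silent in such cells, served as background: their median was 6.36, and 95% of them lay below 8.06. A change with 1 end below 8.06 was read against background, so its size may be understated and its rank among genes is not set. A size from the fit over both cultures is a joint estimate and no bound for either culture. The number of arrays limits the precision of every value.

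The first comparison asked what changed in the first 7 days of conversion. In the fit over both cultures several regulators of the hypoblast came up and the pluripotency factor Sox2 went down. Gata4, a transcription factor of the extraembryonic endoderm, rose by 3.90 ± 0.60 on the log2 scale (SE, adjusted p = 0.00549), Gata6 by 3.42 ± 0.55, Pdgfra, a PDGF receptor, by 3.66 ± 0.67, and Sox17 by 2.94 ± 0.54. Of the 11 hypoblast regulators measured 4 rose, 7 adjusted over the list alone (camera adjusted p = 0.000679; adjusted p = 0.236 with an estimated correlation). Sox2 fell by 1.79 ± 0.46 (adjusted p = 0.0326), and its change was 2.62 higher on feeder cells than without them. The changes to day 7 differed between the cultures. Nanog, which holds cells in the pluripotent state, moved by -3.72 without feeder cells and by -0.06 on feeder cells (adjusted p of that difference 9.56e-07), so that its shared change of -2.28 ± 0.73 did not pass (adjusted p = 0.0669). Pdgfra moved by 5.03 without and 1.54 on feeder cells.

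**Figure D1:**
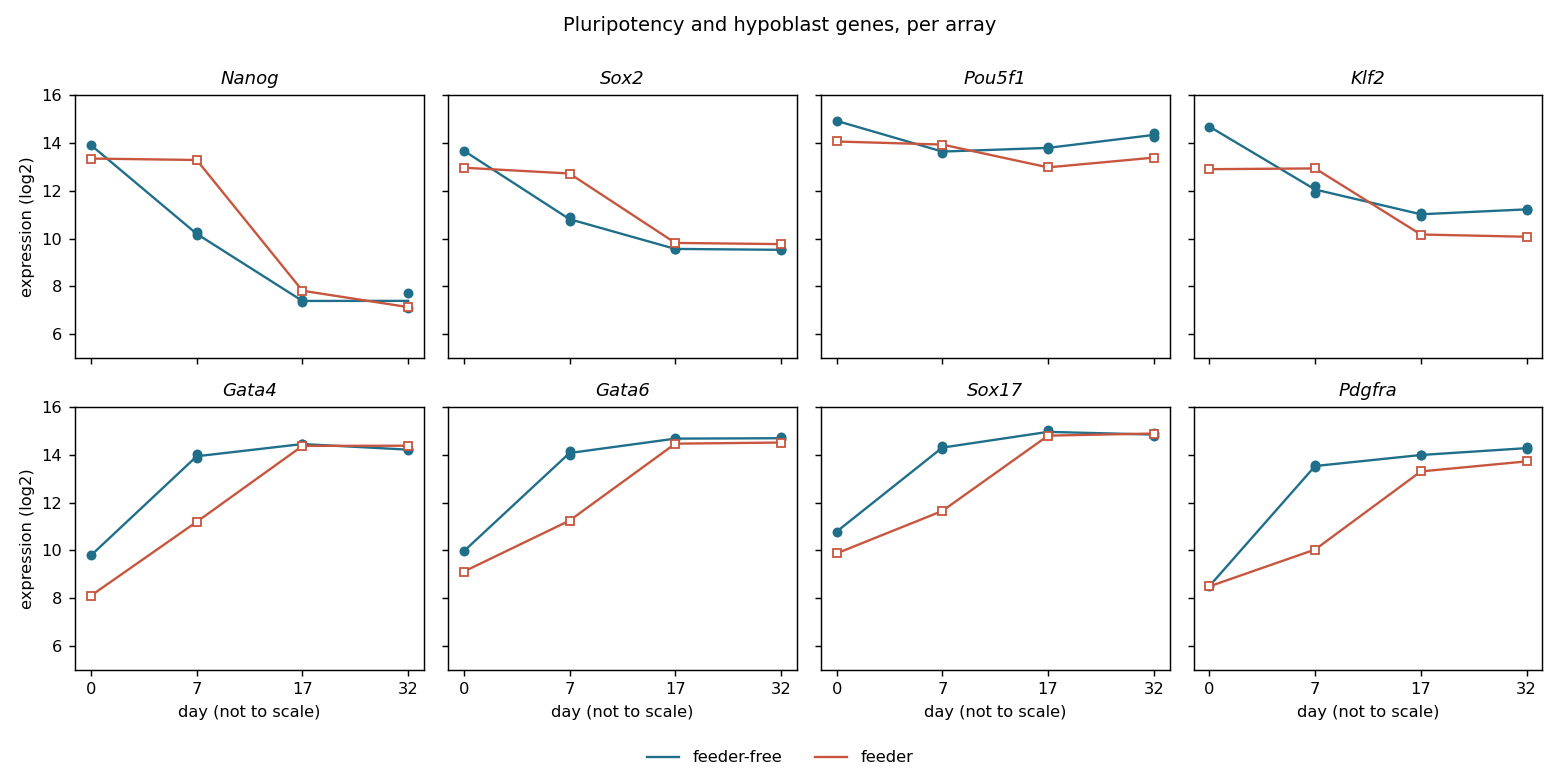
Expression (log2, vertical axis) of 8 genes against day (horizontal axis, not to scale), with 1 point per array and a line through the group means, for feeder-free cells (filled circles, 1 array at day 0 and 2 at each later day) and feeder cells (open squares, 1 array per day). Nanog fell by 3.72 to day 7 without feeder cells against 0.06 on them, a change of -0.06, and the arms lay close together at days 17 and 32.

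Matrix and uptake genes of the extraembryonic endoderm rose, 12 of 16 measured members over all genes and 15 of 16 adjusted over the list alone (camera adjusted p = 8.21e-11; adjusted p = 0.186 with an estimated correlation). Among them were Cubn (4.47 ± 0.38), the endocytic receptor cubilin, Srgn (4.52 ± 0.58), a proteoglycan core protein, and Dab2 (3.21 ± 0.47), an endocytic adaptor. Of the parietal endoderm list 7 of 12 rose, 8 with 1 fall adjusted over the list alone, with Pth1r, a parathyroid hormone receptor, at 3.50 ± 0.82 and Thbd, thrombomodulin, at 2.74 ± 0.68 (camera adjusted p = 2.11e-05; adjusted p = 0.236 with an estimated correlation). Of 10 trophoblast genes 5 rose and 1 fell, 6 and 1 adjusted over the list alone: Plac1 by 3.52 ± 0.62, Elf5 by 3.39 ± 0.26, Hand1 by 2.82 ± 0.41 and Gata3 by 2.78 ± 0.71 (camera adjusted p = 0.00149; adjusted p = 0.236 with an estimated correlation). These list medians moved more without feeder cells than on them. They were 2.54 against 0.62 for matrix and uptake, 2.82 against 0.45 for parietal endoderm and 1.21 against 0.20 for trophoblast. Among the large rises with the same sign in both cultures were Mmp1, a collagenase (5.74 ± 0.95), and the placental prolactin relatives Prl2a1 (5.66 ± 0.53) and Prl7a3 (5.20 ± 0.96). The day 0 values of these 3 genes lay below 8.06 in both cultures. Further large rises were those of Akr1c14 (4.84 ± 0.68), Adgrf5 (4.84 ± 0.93), the tissue factor gene F3 (4.70 ± 0.71) and Cyp17a1, an enzyme of steroid synthesis (4.57 ± 0.88). Of these 4 only F3 lay above 8.06 at day 0.

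Targets of ERK signalling rose in 8 of 17 cases and fell in 1, 10 and 2 adjusted over the list alone (camera adjusted p = 6.29e-06; adjusted p = 0.105 with an estimated correlation). Egr1 rose by 2.44 ± 0.17, Phlda1 by 1.95 ± 0.08 and Fos by 1.76 ± 0.16. Among targets of JAK-STAT signalling 7 of 10 rose and 2 fell, the same counts adjusted over the list alone, led by Socs3 at 3.35 ± 0.29 (camera adjusted p = 0.000836; adjusted p = 0.105 with an estimated correlation). Targets of canonical Wnt signalling fell in 5 of 9 cases, also 5 adjusted over the list alone, with Tnfrsf19 down by 2.49 ± 0.18 and Axin2 down by 2.44 ± 0.24 (camera adjusted p = 0.000641; adjusted p = 0.105 with an estimated correlation). Genes of cholesterol synthesis fell in 9 of 14 cases, 10 adjusted over the list alone with 1 rise, such as Dhcr7 by 1.12 ± 0.12 (camera adjusted p = 0.000199; adjusted p = 0.186 with an estimated correlation). Large falls were those of Crabp1, which binds retinoic acid (-4.37 ± 0.58), Igfbpl1 (-3.26 ± 0.44) and Stag3, a meiotic cohesin subunit (-2.95 ± 0.57). The fibroblast list shifted down with 1 fall of 15, also 1 adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.57 with an estimated correlation). Its median change was -0.05 without and -0.69 on feeder cells. Without the feeder day 0 array the list turned upward, so the shift down depends on that array. The germline list had 7 of 13 falls and 1 rise, 8 and 1 adjusted over the list alone, with Asz1 at -1.59 ± 0.16 and Dazl at -1.42 ± 0.15 (camera adjusted p = 0.00149; adjusted p = 0.236 with an estimated correlation).

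In all, 2322 of 14506 genes changed from day 0 to day 7 in limma, 977 up and 1345 down. Among those changed by at least 1 on the log2 scale 492 rose and 345 fell. In the cultures 3193 genes changed by different amounts. The count was 684 without the feeder-free day 0 array, 991 and 1129 without the first and the second feeder-free day 7 array, and 4448 without the feeder day 7 array. It was 5348 with the feeder-free arrays alone.

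**Figure D2:**
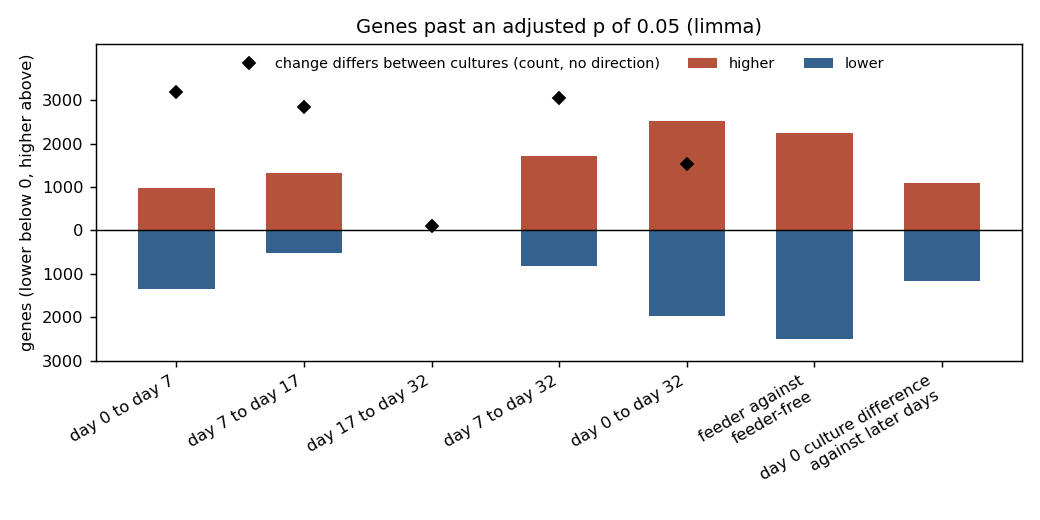
Number of genes past an adjusted p of 0.05 in limma (vertical axis, genes higher above 0 and lower below 0) for each comparison (horizontal axis), over 14506 genes. Black diamonds give the number of genes whose change differed between the cultures, 3193 from day 0 to day 7 and 99 from day 17 to day 32.

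From day 7 to day 17 the trophoblast genes Elf5, Gata3 and Hand1, which had risen to day 7, fell. Nanog and Sox2 fell as well. Elf5 fell by 4.24 ± 0.23 (adjusted p = 0.000122), Gata3 by 3.14 ± 0.63, Hand1 by 3.08 ± 0.37 and Tfap2c by 2.38 ± 0.21. Of the 10 trophoblast genes 5 fell and 1 rose, 7 and 1 adjusted over the list alone (camera adjusted p = 5.96e-07; adjusted p = 0.191 with an estimated correlation). Mmp1 fell by 5.89 ± 0.85, Prl2a1 by 5.58 ± 0.47, Prl7a3 by 5.26 ± 0.85 and Cyp17a1 by 4.61 ± 0.78. These 4 genes ended below 8.06 in both cultures. Nanog fell by 3.70 ± 0.65 and Sox2 by 1.80 ± 0.41, both with a larger fall on feeder cells (-5.47 against -2.81 for Nanog). Nanog at day 17 lay below 8.06. Of the 16 naive pluripotency genes 4 fell and 1 rose, 7 and 2 adjusted over the list alone (camera adjusted p = 0.00298; adjusted p = 0.38 with an estimated correlation). The list median was -0.37 without and -1.96 on feeder cells.

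**Figure D3:**
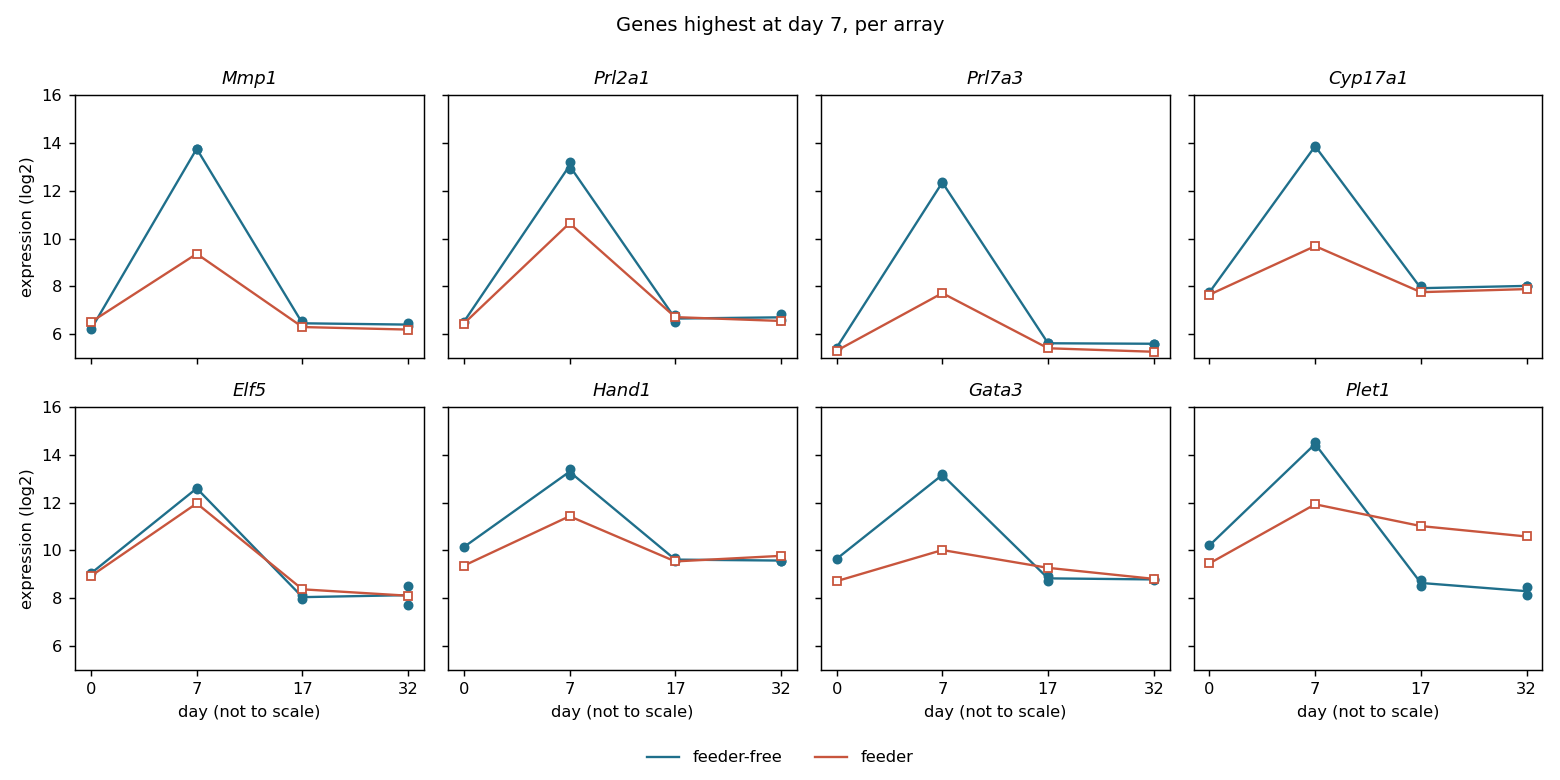
Expression (log2, vertical axis) against day (horizontal axis, not to scale) of 8 genes with their highest value at day 7, with 1 point per array and a line through the group means, for feeder-free cells (filled circles) and feeder cells (open squares). Mmp1 moved by 7.56 from day 0 to day 7 in feeder-free cells and by 2.86 in feeder cells.

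The other large falls were those of Lcp1, an actin-bundling protein (-4.87 ± 0.17), Fndc3c1 (-4.48 ± 0.71), the germ cell gene Tex15 (-4.23 ± 0.31), Plet1 (-4.18 ± 0.94) and Slc38a3, an amino acid transporter (-4.09 ± 0.30). At day 17 Fndc3c1 lay below 8.06 in both cultures and Tex15 without feeder cells. Among the rises were Cmahp at 3.11 ± 0.40, Pga5, a pepsinogen, at 2.86 ± 0.32, Galnt3 at 2.36 ± 0.15 and Tspan8 at 2.31 ± 0.25. On feeder cells Cmahp, Galnt3 and Tspan8 began below 8.06. Of the ERK targets 5 of 17 fell, 8 adjusted over the list alone (camera adjusted p = 1.56e-07; adjusted p = 0.0897 with an estimated correlation), with Egr1 at -1.67 ± 0.15 and Ier3 at -1.45 ± 0.10. Matrix and uptake genes rose in 4 of 16 cases, also 4 adjusted over the list alone (camera adjusted p = 0.00527; adjusted p = 0.575 with an estimated correlation), among them Lrp2, or megalin, at 1.04 ± 0.25. Hypoblast regulators had 1 rise of 11, that of Foxq1, and 5 adjusted over the list alone. Gata4 moved by 0.51 without and 3.18 on feeder cells (adjusted p of the difference 1.97e-07). The imprinted genes fell in 4 of 12 cases, also 4 adjusted over the list alone, with Mest at -1.86 ± 0.21 (camera adjusted p = 0.00563; adjusted p = 0.264 with an estimated correlation).

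Between days 7 and 17, 1850 genes changed in limma, 1320 up and 530 down. The split became 633 and 628 with a further quantile normalization, and 153 and 281 among those changed by at least 1 on the log2 scale. In the cultures 2852 changed by different amounts. The count was 455 without the feeder day 17 array, 798 without the first feeder-free day 7 array, 493 and 364 without the first and the second of day 17, 1001 and 1157 without those of day 32, and 3458 with the feeder-free arrays alone.

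From day 17 to day 32 no gene passed in the limma model with terms for day and culture over all 11 arrays, and 1057 genes had an unadjusted p under 0.05. None of the 7 always reported genes passed: Pou5f1 moved by 0.50 ± 0.24 (adjusted p = 0.731), Sox2 by -0.04 ± 0.41, Nanog by -0.23 ± 0.65, Gata4 by -0.15 ± 0.54, Gata6 by 0.03 ± 0.49, Sox17 by -0.05 ± 0.48 and Pdgfra by 0.33 ± 0.60. The spread in that model included the distance between the cultures at day 7. With the arrays of days 17 and 32 alone, an alternative chosen after seeing the data, 794 genes passed, 201 up and 593 down.

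Of the gene lists the mesenchymal one shifted down (camera adjusted p = 5.98e-06; adjusted p = 0.649 with an estimated correlation), with 0 of 14 members past the test over all genes and 5 falls adjusted over the list alone. Its largest changes were those of Cnn1, calponin (-1.19 ± 0.21, adjusted p = 0.15), and Cdh2, N-cadherin (-0.92 ± 0.31). ERK targets also shifted down (camera adjusted p = 0.000903; adjusted p = 0.486 with an estimated correlation), with 0 of 17 members past the test and 4 falls adjusted over the list alone. Dusp4, a phosphatase that is induced by ERK, moved by -1.44 ± 0.23 and Ccnd1, cyclin D1, by -1.18 ± 0.36. Cholesterol synthesis (camera adjusted p = 0.0242; adjusted p = 0.858 with an estimated correlation) and glycolysis (camera adjusted p = 0.0139; adjusted p = 0.858 with an estimated correlation) shifted up with no member past either adjustment. The change differed between the cultures for 99 genes, among them S100a4 with -0.09 without and -2.12 on feeder cells. The count of genes changed was 934 with each day and culture as its own group, 1062 with the feeder-free arrays alone, 232 without the feeder day 7 array, 14 without either day 0 array, and 7 and 10 without the feeder arrays of days 17 and 32.

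Over the longer interval from day 7 to day 32 the ERK targets fell as a group. Of 17 measured 11 fell, 12 adjusted over the list alone, and this was the only list shift of all comparisons that held with an estimated correlation (camera adjusted p = 1.39e-10; adjusted p = 0.0383 with an estimated correlation). Myc fell by 2.66 ± 0.58, Fosl1 by 2.42 ± 0.59, Dusp6, a phosphatase that acts on ERK, by 2.37 ± 0.57 and Etv5 by 2.21 ± 0.29. Trophoblast genes fell in 6 of 10 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 2.56e-05; adjusted p = 0.251 with an estimated correlation). Large falls of single genes to values below 8.06 were those of Mmp1 (-5.97 ± 0.85), Prl2a1 (-5.60 ± 0.47) and Lcp1 (-5.23 ± 0.17).

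Mesenchymal genes fell in 4 of 14 cases, also 4 adjusted over the list alone, with Fn1, fibronectin, at -2.57 ± 0.24 and Zeb1 at -0.95 ± 0.14 (camera adjusted p = 1.04e-05; adjusted p = 0.251 with an estimated correlation). The median of that list moved from day 7 to day 17 by 0.10 without and -0.41 on feeder cells. The fibroblast list, with a median excess of 0.78 on feeder cells at day 7, shifted the same way with 1 fall of 15, also 1 adjusted over the list alone (camera adjusted p = 0.047; adjusted p = 0.668 with an estimated correlation). Cholesterol synthesis genes rose in 6 of 14 cases, 8 adjusted over the list alone, by small amounts such as 0.48 ± 0.10 for Cyp51 (camera adjusted p = 0.00573; adjusted p = 0.333 with an estimated correlation). Large rises were those of Cmahp (3.37 ± 0.40), Sh3gl3 (3.04 ± 0.34), Krt4, a keratin (3.03 ± 0.23), and Igf1 (2.68 ± 0.34). On feeder cells Cmahp and Krt4 began below 8.06. Hnf4a, a transcription factor of the visceral endoderm, rose by 1.07 ± 0.23 and Foxq1 by 1.77 ± 0.39. In limma 2535 genes changed, 1719 up and 816 down. The split became 1261 and 1040 with a further quantile normalization, and 189 and 366 among those changed by at least 1 on the log2 scale. In the cultures 3050 changed by different amounts. The count was 770 and 1281 without the first and the second feeder-free day 32 array, 1436 without the first feeder-free day 7 array, 1114 without the feeder day 32 array, and 4101 with the feeder-free arrays alone.

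From day 0 to day 32 Nanog fell in both cultures, and Gata4, Gata6, Sox17 and Pdgfra rose in both. Nanog fell by 6.20 ± 0.73 (adjusted p = 0.000583), from 13.92 to a mean of 7.39 ± 0.45 (SD, n = 2) without feeder cells and from 13.35 to 7.13 on them, where the latter values lay below the 8.06 that bounds 95% of the receptor genes. Sox2 fell by 3.63 ± 0.46. Gata4 rose by 5.15 ± 0.60, Gata6 by 4.93 ± 0.55, Pdgfra by 5.39 ± 0.67 and Sox17 by 4.38 ± 0.54. Pou5f1, which encodes the pluripotency factor Oct4, did not pass, at -0.57 ± 0.27 (adjusted p = 0.151). Across genes the changes in both cultures correlated at 0.827, with genes not being independent replicates.

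Of the naive pluripotency list 9 of 16 fell and 2 rose, 11 and 2 adjusted over the list alone, with Gdf3 at -3.83 ± 0.72 and Klf2 at -3.06 ± 0.49 (camera adjusted p = 0.00219; adjusted p = 0.443 with an estimated correlation). Primed epiblast genes fell in 4 of 9 cases and rose in 1, 5 and 1 adjusted over the list alone, with Lef1 at -4.09 ± 0.47 and Nodal at -2.52 ± 0.45 (camera adjusted p = 0.0347; adjusted p = 0.467 with an estimated correlation). Hypoblast regulators rose in 8 of 11 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00413; adjusted p = 0.467 with an estimated correlation). Matrix and uptake genes rose in 15 of 16 cases, also 15 adjusted over the list alone, led by Cubn at 6.03 ± 0.38 and Srgn at 5.58 ± 0.58 (camera adjusted p = 7.58e-08; adjusted p = 0.42 with an estimated correlation). Parietal endoderm genes rose in 8 of 12 cases and fell in 1, 9 and 1 adjusted over the list alone, with Pth1r at 5.27 ± 0.82 and Stra6 at 3.22 ± 0.66 (camera adjusted p = 0.00508; adjusted p = 0.487 with an estimated correlation). The visceral endoderm list had 3 rises and 3 falls of 17, the same adjusted over the list alone, and did not shift (camera adjusted p = 0.674), with Ihh at 3.22 ± 0.38 and Hhex at -2.49 ± 0.33. Among the other large rises were Sema6d (5.92 ± 0.87), the chemerin receptor Cmklr1 (5.90 ± 0.58) and P3h2, a collagen prolyl hydroxylase (5.58 ± 0.78). P3h2 began below 8.06 in both cultures, the other 2 without feeder cells. Large falls beside Nanog were those of Ly6c (-6.26 ± 0.85) and the neurofilament gene Nefl (-5.50 ± 0.70), both to values below 8.06. Others were those of Slc7a3, an amino acid transporter (-5.32 ± 0.38), and Crabp1 (-5.31 ± 0.58).

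Germline and DNA methylation genes fell in 11 of 13 cases and rose in 1, the same adjusted over the list alone, with Dazl at -3.21 ± 0.15 and Mael at -2.95 ± 0.44 (camera adjusted p = 2.49e-05; adjusted p = 0.42 with an estimated correlation). Wnt targets fell in 6 of 9 cases, also 6 adjusted over the list alone (camera adjusted p = 3.52e-05; adjusted p = 0.0886 with an estimated correlation), and JAK-STAT targets rose in 7 of 10 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00882; adjusted p = 0.384 with an estimated correlation). Glycolysis genes fell in 7 of 16 cases and rose in 1, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0044; adjusted p = 0.487 with an estimated correlation), with Pgk1 at -1.42 ± 0.26. Cell cycle genes fell in 6 of 16 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.00409; adjusted p = 0.487 with an estimated correlation), with Cdk1 at -0.70 ± 0.11. Fibroblast genes shifted down with 2 falls of 15, also 2 adjusted over the list alone (camera adjusted p = 0.00378; adjusted p = 0.487 with an estimated correlation), and all 15 had been higher on feeder cells at day 0. The shift did not pass for the lists of mesendoderm and mesoderm (0 of 14 changed, camera adjusted p = 0.895), neuroectoderm (1 rise and 3 falls of 10, 0.09), epithelial junctions and keratins (4 and 3 of 13, 0.817), BMP targets (2 and 3 of 12, 0.338), cholesterol synthesis (2 and 4 of 14, 0.0915), imprinted genes (4 and 4 of 12, 0.951) or interferon and antigen presentation (4 rises of 14, 0.09). Nor did the shift pass for ERK targets (4 rises and 1 fall of 17, camera adjusted p = 0.817), trophoblast (2 and 3 of 10, 0.442) or mesenchymal genes (3 and 3 of 14, 0.404). Adjusted over the list alone these counts were the same except for 6 falls in cholesterol synthesis and 5 rises among imprinted genes. Phlda2, an imprinted gene that restrains placental growth, rose by 5.08 ± 0.45.

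In limma 4504 genes changed from day 0 to day 32, 2522 up and 1982 down. The split became 2286 and 2359 with a further quantile normalization. In the cultures 1538 genes changed by different amounts, Gata4 among them (4.43 without and 6.28 on feeder cells). The count was 2536 without the feeder-free day 0 array.

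The next comparison set the feeder arm against the feeder-free arm over all 4 days. Cav1, caveolin, was higher by 2.81 ± 0.26 (adjusted p = 7.47e-05) on feeder cells, and so were S100a4 (2.50 ± 0.45), Pmp22 (2.33 ± 0.29) and Thbs1, thrombospondin (2.27 ± 0.69). Such a size is joint over the 4 days and need not be constant. Cav1 stood at 11.14 on feeder cells and 7.18 without them at day 0, and at 10.54 and 8.35 at day 32. S100a4 is a member of the fibroblast list. Subunits of the mitochondrial respiratory complex I stood among the top genes: Ndufb6 was higher by 2.61 ± 0.10, Ndufs4 by 2.30 ± 0.10 and Ndufc2 by 2.06 ± 0.06. Lower on feeder cells were Ehd3 (-2.20 ± 0.17), Nexn (-2.05 ± 0.34), Tomm40, of the mitochondrial import pore (-1.83 ± 0.05), and the ribosomal protein gene Rpl22 (-1.74 ± 0.05). The offset of Ndufb6 was 2.33, 2.82, 2.40 and 2.81 at days 0, 7, 17 and 32, and that of Tomm40 was -1.90, -1.75, -1.85 and -1.84.

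Among ERK targets 10 of 17 were higher and 1 lower, 10 and 2 adjusted over the list alone, with Ccnd1 at 1.72 ± 0.28 and Dusp6 at 1.56 ± 0.44 (camera adjusted p = 0.0479; adjusted p = 0.856 with an estimated correlation). Dusp6 stood at 11.19 on feeder cells and 7.52 without them at day 0, but at 8.15 and 7.68 at day 32. Of the fibroblast list 5 of 15 were higher, 8 adjusted over the list alone, among them Prrx1 at 1.56 ± 0.42 and Twist2 at 1.15 ± 0.18 (camera adjusted p = 0.0152; adjusted p = 0.856 with an estimated correlation). The median excess of the fibroblast list was 1.25 at day 0, 0.78 at day 7, 0.11 at day 17 and 0.03 at day 32. Snai2, a mesenchymal transcription factor, was higher by 1.88 ± 0.36. Matrix and uptake genes were lower in 5 of 16 cases, also 5 adjusted over the list alone, such as Col4a1 at -1.81 ± 0.50, without a list shift (camera adjusted p = 0.175). For Klf4 the brighter of 2 probe sets gave -0.44 and the other 0.63.

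**Figure D4:**
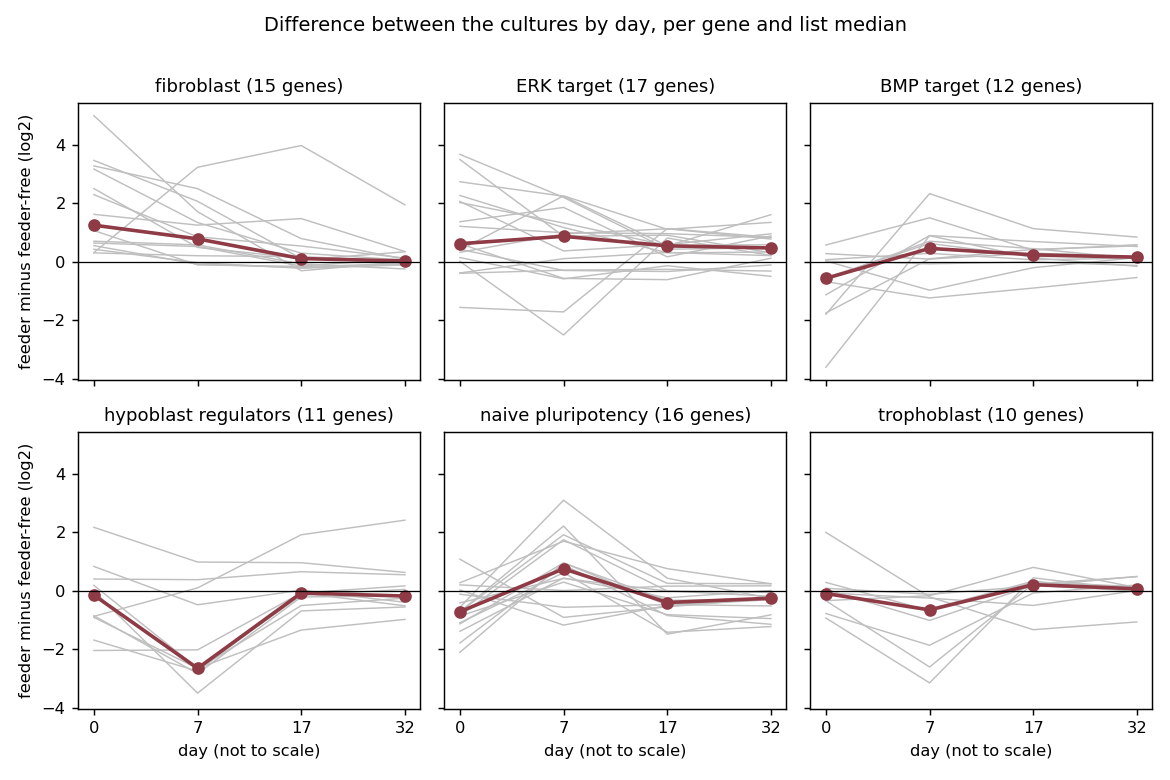
Difference between feeder and feeder-free cells (log2, vertical axis, feeder minus the feeder-free mean) against day (horizontal axis, not to scale) for 6 gene lists, with a grey line per gene and a red line through the list medians. The median of the fibroblast list fell from 1.25 at day 0 to 0.03 at day 32, and that of the hypoblast regulators was -2.65 at day 7.

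In limma 4749 genes differed between the arms, 2249 higher and 2500 lower on feeder cells. Among those with a difference of at least 1 on the log2 scale 275 were higher and 195 lower. Among the 1240 receptor genes used as background 11.1% differed, against 32.7% of all genes, and 132 of these 138 were lower on feeder cells (median of all receptor genes -0.10).

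The last comparison asked where the cultures differed at day 0 in another way than later. The feeder array carried higher levels of fibroblast genes. Vim, the mesenchymal filament vimentin, stood at 14.57 on feeder cells and 8.69 without them at day 0, and its difference between the cultures exceeded that of the later days by 5.76 ± 0.16 (adjusted p = 1.19e-10). Postn, periostin, exceeded it by 4.52 ± 0.17, Bgn, biglycan, by 4.22 ± 0.16, Trh by 4.16 ± 0.22 and Timp2 by 3.87 ± 0.16. Id1, a target of BMP signalling, stood at 12.93 without feeder cells and 9.33 on them, and its difference lay below that of the later days by -3.89 ± 0.15.

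Of 15 fibroblast genes 12 were above and 1 below the later difference, 13 and 1 adjusted over the list alone, with Mmp2 at 2.74 ± 0.17 and Col1a1 at 2.60 ± 0.21 (camera adjusted p = 4.1e-11; adjusted p = 0.107 with an estimated correlation). BMP targets were below it in 6 of 12 cases, also 6 adjusted over the list alone, with Id2 at -3.22 ± 0.19 and Msx2 at -2.11 ± 0.17 (camera adjusted p = 0.000117; adjusted p = 0.37 with an estimated correlation). The median difference of the BMP targets was -0.57 at day 0, but 0.46, 0.24 and 0.16 at days 7, 17 and 32. At day 0, 5 of the 12 were higher on feeder cells, so the later days contributed to this shift. ERK targets were above in 9 of 17 cases and below in 4, 10 and 4 adjusted over the list alone, with Etv4 at 2.80 ± 0.19, Dusp6 at 2.63 ± 0.17 and Myc at -1.64 ± 0.16 (camera adjusted p = 0.000187; adjusted p = 0.37 with an estimated correlation). Dusp6 itself was at 7.52, below 8.06, without and 11.19 on feeder cells at day 0. The median difference of the ERK targets was 0.62 at day 0, and 0.87, 0.55 and 0.47 at days 7, 17 and 32. At day 0 this median thus did not exceed that of day 7. Naive pluripotency genes were below in 9 of 16 cases and above in 2, 12 and 3 adjusted over the list alone, with Fgf4 at -2.22 ± 0.16, Nanog at -1.65 ± 0.25 and Lin28a at 1.65 ± 0.17 (camera adjusted p = 0.000117; adjusted p = 0.401 with an estimated correlation). Part of this came from the later days, since Nanog was higher on feeder cells by 3.09 at day 7 and lower by 0.56 at day 0, a difference of -0.56. The parietal endoderm list (9 of 12 above and 1 below, the same adjusted over the list alone, camera adjusted p = 1.51e-09; adjusted p = 0.37 with an estimated correlation) shifted upward. So did matrix and uptake genes (9 of 16 above, 11 with 2 below adjusted over the list alone, camera adjusted p = 7.57e-09; adjusted p = 0.401 with an estimated correlation). The median differences of these lists were 0.20 and 0.08 at day 0 but -1.68 and -1.71 at day 7, so day 7 contributed to both shifts. Vim, a member of the parietal endoderm list, differed at day 0 itself, as given above. Mesenchymal genes were above in 8 of 14 cases and below in 1, the same adjusted over the list alone (camera adjusted p = 1.89e-08; adjusted p = 0.37 with an estimated correlation). Imprinted genes were above in 7 of 12 cases and below in 1, 7 and 2 adjusted over the list alone (camera adjusted p = 2.18e-05; adjusted p = 0.37 with an estimated correlation). Their medians were 0.68 and 0.66 at day 0, and 0.46 and -0.09 at day 7. Genes of DNA methylation and the germline were below in 5 of 13 cases, also 5 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.401 with an estimated correlation). Their median difference was -0.28 at day 0, and 0.43, -0.20 and 0.02 at days 7, 17 and 32, so day 7 contributed to this shift. The imprinted growth factor Igf2 was above by 3.00 ± 0.16 and the trophoblast gene Cdx2 by 2.86 ± 0.16. The epithelial genes Cldn4 and Cdh1, E-cadherin, were below by -3.28 ± 0.18 and -1.45 ± 0.17. Cldn4 stood at 11.73 without and 10.72 on feeder cells at day 0, but at 11.87 and 13.46 at day 7. Cdh1 stood at 13.62 and 12.96 at day 0, and at 11.99 and 13.64 at day 7. Both contrasts thus came in large part from later days. The epithelial list had 4 above and 6 below of 13, without a list shift (camera adjusted p = 0.138).

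In limma 2249 genes had such a difference, 1086 above and 1163 below. The split became 1386 and 1275 with a further quantile normalization, and 403 and 356 among those with a difference of at least 1 on the log2 scale. Each culture had 1 array at day 0, so the spread came from the feeder-free replicates of later days alone.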

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

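The tests of exchanged arrays, of a shrinking of changes common to the feeder arrays, of genes that peaked at day 7, of feeder-cell RNA and of the fibroblast genes were chosen after the result was seen. For the genes that peaked at day 7 the bound itself was changed after the value was seen, since the first bound left it undecided. The mixture test of the remaining genes was set before, and the genes it covers were worded more narrowly afterwards.

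Genes moved by different amounts in the cultures in every interval, by a test of that difference in limma: 3193 from day 0 to day 7, 2852 from day 7 to day 17, 99 from day 17 to day 32, 3050 from day 7 to day 32 and 1538 from day 0 to day 32. The counts of the intervals with day 7 all rest on the same single feeder array and are not separate evidence. Of the named genes 69 of 94, 50 of 78, 3 of 50, 52 of 85 and 42 of 98 had such a difference. Most were named for large changes, so these shares cannot be set against that of all genes. For the change from day 0 to day 7, feeder minus feeder-free, the values were 3.66 for Nanog, 2.62 for Sox2, 1.16 for Pou5f1, -1.06 for Gata4, -1.98 for Gata6, -1.74 for Sox17 and -3.48 for Pdgfra.

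The feeder array of day 7 thus lay near day 0. Exchanged arrays of days 0 and 7 are argued against, since 78.5% of the 963 genes at least 2-fold higher at day 7 without feeder cells were higher at day 7 on feeder cells too. A shrinking of changes common to the feeder arrays is also argued against, since the slope of feeder on feeder-free changes was 0.249 to day 7 but 0.789 to day 17 and 0.794 to day 32. A constant offset of all feeder arrays cancels in such changes, so the slopes do not test it. A mixture of day 0 cells with cells already at the state of days 17 and 32 gave a converted share of 7.05% (quartiles 3.59 and 12.5) from 133 rising genes. From 84 falling genes the share was 36.5% (quartiles 7.91 and 60.2), so the ranges overlap while the medians lie apart. The falling genes were not cleared of possible feeder-cell RNA in the day 0 array. Bgn, for example, stood at 13.73 at day 0 and at 9.43 and 9.32 at days 17 and 32 on feeder cells. The overlap thus decides little. Such a mixture is argued against for 25 genes with a peak at day 7, whose median feeder peak was 1.12 on the log2 scale. Of these, 15 were over 2-fold, all in the 1 feeder array of day 7. The 95% limits of that median, 0.75 and 1.89, treat the genes as independent and do not measure spread between arrays. A mixture with cells at the feeder-free day 7 state and a slower conversion in the feeder arm may remain, untested with 1 array.

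Differences between the cultures of the same sign on all 4 days are the second pattern. RNA of feeder cells is argued against for the differences at day 32, where 9 fibroblast genes at least 2-fold higher at day 0 had a median difference of 0.0574 (highest 0.35), against 1.13 (lower quartile 0.85) for the 262 genes of the pattern at least 2-fold higher on feeder cells. For day 0 it stays open: the median ratio of the day 32 to the day 0 difference, 0.941, decides nothing, since those genes were picked for a lasting difference, and that of Pmp22 went from 3.50 to 1.15. Separate handling of the arms cannot be told apart from culture, itself untested, as every feeder array belongs to 1 arm. Of the receptor genes 11.1% differed, 132 of 138 of them lower on feeder cells, against 32.7% of all genes. In the comparisons of days 0% to 2.5% of the receptor genes changed. The lowest value of an array was 4.33 to 4.38 in the feeder arm and 4.40 to 4.48 in the feeder-free arm. Of the 54 choices of 1 array per day as the feeder array, 1, the real one, gave as many genes (4749, highest other 2). A wrong choice moves the difference between the arms into the residual spread, so its low count follows from any such difference. The counts show that the arrays of the arms differ, but do not tell handling from culture.

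The third pattern is the fibroblast genes of the feeder day 0 array. All 15 measured, 100% of the list, were higher than without feeder cells, by a median of 1.25, and the excess was 0.0270 at day 32, so RNA of the mouse feeder layer may be the source. Postn, Bgn and Vim were among the genes with large differences. A handling difference shared by all feeder arrays is argued against here, since it would have kept the excess. Handling of the feeder day 0 array alone was not tested. A response of the rat cells to the layer stays open, untested.

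Probe sets without a gene symbol here were outside the comparisons: of 13581, 4628 differed between the cultures and 2086 changed from day 0 to day 32, or 34.1% and 15.4%.

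For the splits of 6 arrays of a pair of days, 10 are too few for a share under 0.05. The real split gave 1850 genes from day 7 to day 17 (highest other 0, 1 of 10 as large), 0 from day 17 to day 32 (highest other 0, 10 of 10 as large) and 2535 from day 7 to day 32 (highest other 4, 1 of 10 as large).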

How the results depend on the processing

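The fits without both the feeder day 0 and day 7 arrays, and with days 17 and 32 only, were chosen after seeing the data. The cause of the shifts below was not tested, except that asking for a change of at least 1 on the log2 scale passes fewer genes by construction, and that the table of all probe sets holds more of them. Signal near the receptor-gene level of 8.06 limits what dim genes can show.

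From day 0 to day 7 (2322 genes) the count was 837 with a change of at least 1, 4887 with 8 groups, 805 without a culture term, 5348 with feeder-free arrays, 5156 without both early feeder arrays, and 684 to 4448 leaving out 1 array. With the replicate block it was 1325, and 984 from day 7 to day 17, but the deviations of equal replicate numbers correlated at only 0.034, -0.195 and -0.0991, so the numbers are not shown to pair the samples.

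From day 7 to day 17 (1850) it was 2852 with array weights, 434 with a change of at least 1, 5347 with 8 groups, 266 without a culture term, 3458 with feeder-free arrays, 3291 without both early feeder arrays, and 364 to 2344 leaving out 1 array. From day 17 to day 32 (0 in limma, 1057 at an unadjusted p under 0.05) it was 792 with array weights, 934 with 8 groups, 1062 with feeder-free arrays, 869 without both early feeder arrays, 794 with days 17 and 32 only, and 0 to 232 leaving out 1 array. From day 7 to day 32 (2535) it was 555 with a change of at least 1, 5752 with 8 groups, 587 without a culture term, 4101 with feeder-free arrays, 4090 without both early feeder arrays, and 770 to 2982 leaving out 1 array.

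From day 0 to day 32 (4504) it was 1727 with a change of at least 1, 2573 without a culture term, and 2536 to 5528 leaving out 1 array. Feeder against feeder-free (4749) gave 9904 over all probe sets, 470 with a change of at least 1, 7699 with 8 groups, and 3738 to 4970 leaving out 1 array. The day 0 contrast (2249) gave 759 with a change of at least 1 and 2171 to 2389 leaving out 1 array.

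The number of list calls, 67, was 1 with an estimated correlation, 57 with fry (24 lost and 14 new), 58 without the dim 25% of genes, and 65 to 69 leaving out 1 array where all comparisons could be fitted. Klf4 turned from -0.44 to 0.0933 between the cultures with the mean of its probe sets. From day 0 to day 7 leaving out 1 array gave adjusted p of 4.56e-08 to 0.487 for the fibroblast list and 0.00555 to 0.953 for the BMP targets, and without the feeder day 0 array the former turned upward, at 0.487, and the latter downward, at 0.0489. No other called result for a named gene or list reversed under the alternatives run. Of the medians of lists and families, most near 0, 23 changed sign with centring and 13 with a further quantile normalization. The median change of all genes lay between -0.10 and 0.11 under each scaling.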

Other observations

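The gene families and the genes with a peak at day 7 below were chosen after the values were seen. Some genes of placental hormones and steroid synthesis, picked from these values and not tested as a group, rose to day 7 and fell to day 17. Of 21 genes of the prolactin family 4 rose to day 7, 5 fell to day 17 and 7 fell from day 7 to day 32, with medians of 0.08, -0.04 and -0.10. Star, which brings cholesterol into mitochondria, rose by 2.66 ± 0.49 (adjusted p = 0.0103) and then moved by -2.52 ± 0.44, and Hsd3b2, a steroid dehydrogenase, rose by 3.48 ± 0.69 and then moved by -3.30 ± 0.61. Cdh5, the cadherin of endothelial cells, moved by 3.42 ± 0.72 and -3.76 ± 0.64, and Car4, a carbonic anhydrase, by 3.72 ± 0.24 and -2.90 ± 0.21.

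Over all genes 32.7% differed between the cultures, 2249 higher and 2500 lower on feeder cells. The families below were not tested as groups. Of 32 subunits of respiratory complex I 21 were higher and 3 lower on feeder cells, with a median of 0.41, and of 67 ribosomal protein genes 20 were higher and 35 lower, with a median of -0.21. Of 24 integrins, receptors for matrix, 10 had a higher feeder difference at day 0 than later and 0 a lower one.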
